A study of Mus musculus with 27 samples.

How the data were processed

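Expression was measured in 27 mouse libraries in 13 groups. The 21 full-length libraries (polyA-selected, TruSeq kit, paired reads) form 10 groups of 2 libraries, or 3 for iMN, and the 6 3′-DGE libraries form 3 groups of 2. For the full-length libraries the deposited values are expected counts: estimated fragments per Ensembl gene before scaling, in the layout of a Cuffdiff tracking table. The labels name TopHat2 2.0.7, Bowtie2 2.0.5, Cufflinks 2.1.1 and the mm10 build, without saying which step each served. For the 3′ libraries the deposited values are whole-number counts per gene symbol, in a single table. The labels name Trimmomatic 0.36 and STAR 2.5.3a for them, and the program that counted is not given in the sources used here, nor is the annotation release of either set. The 3′ table holds 16054 genes, 952 of them at 0 in all 6 libraries. Of the 15330 found in the annotation, 1 lies on X or Y. The labels number the samples as the 6 columns are numbered.

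Each full-length table held 28670 genes. The 20 with a status other than OK were left out and 28650 used. Expected counts were rounded to whole numbers. Symbols were given to 25236 Ensembl IDs, and 3414 had none (at most 1.28% of a library's fragments). They stayed in the fits but were not named. Coordinates are from GENCODE M21, on the mm10 assembly. Library totals ran from 6327059 to 30721412 (full-length) and from 18919827 to 39582212 (3′). The level that 3 counts allow ran from 0.0778 to 0.468 CPM over the libraries. The floor for a group at 0 is the mean of this level over its libraries.

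The library sets were fitted separately, each with all its groups in 1 model, using edgeR 4.0.16 (limma 3.58.1, R 4.3.3): filterByExpr, TMM factors, robust quasi-likelihood tests and Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. This tested 17045 and 13757 genes, with 11 and 3 residual degrees of freedom and a common biological coefficient of variation of 0.247 and 0.774. The standard error of a log2 fold change is its size over the square root of F. A fold against a group with 0 counts is given as a bound (at least), from a floor of 3 counts per library. For a group with 1 to 3 counts the comparisons give only levels.

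The comparisons, tests, 30 gene lists, alternatives and the rule for naming genes were fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists. Members are counted after adjustment over all genes and over the list alone. A list's median is also given with genes at 0 counts set to their bound. The lists cover motor neuron identity, transduced factors, pan-neuronal genes, channels and receptors, axon guidance, Hox paralogs 1 to 5, 6 to 8 and 9 to 13, neural progenitor, spinal interneuron, pluripotency, fibroblast and matrix, NF-kB pathway, interferon and antigen presentation, astrocyte and oligodendrocyte, Schwann and neural crest, microglia and macrophage, endothelial, erythroid, skeletal and cardiac muscle, proliferation, cholesterol synthesis, hypoxia and glycolysis, ER and amino acid stress, immediate early, p53 targets, retinoic acid response, hedgehog response, imprinted and motor neuron disease genes. Which lists are described for each comparison was chosen after the list results were seen.

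Named genes are, per comparison, the 6 largest rises and falls by fitted log2 fold change, which for groups at 0 counts depends on the prior count (4 in the other comparisons), among genes that passed, had a mean of at least 10 CPM in the higher group and did not overlap between the groups' libraries; up to 4 members of each described list with the smallest adjusted p and up to 2 that did not pass; and always Mnx1, Isl1, Chat, Tubb3, Pou5f1, Nanog and Col1a1. Genes named by library outside these comparisons were chosen after their values were seen.

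Positions between source cells and E13.5 MN are projections of log2 CPM (prior count 2) on the line between the group means, and Spearman correlations are over the genes tested. For genes shared by comparisons with common controls, groups without a true change were simulated around the same controls in 20 draws. Tables were summarised with Python 3.11.15 (pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9). The fits were tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. They recovered 20% and 91% of these for ESC-MN against E13.5 MN (5 false of 116 calls), 40% and 91% for iMN against E13.5 MN (5 of 136), 17% and 86% for iPSC against ESC (10 of 113), 2% and 47% for conditioned against control medium (3 of 52), and 1% and 50% for control-medium ESC-MN against E11.5 MN (8 of 59).

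The alternatives were RLE scaling, no filter, only the groups compared in the fit, an added absolute log2 fold change of at least 1, DESeq2 1.42.0, the style of the sample titles (3 styles) as a term, replicate number as a block, a prior count of 0.5, other MEF references, an estimated correlation, and leaving out each library in turn. Scaled fragments and FPKM columns of the full-length tables were not used, since tests need counts.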

Results

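RNA was measured in 27 mouse libraries that fall into 13 groups. Of these, 21 full-length libraries in 10 groups cover embryonic stem cells (ESC), induced pluripotent stem cells (iPSC), motor neurons (MN) differentiated from each of them, motor neurons converted directly from mouse embryonic fibroblasts (iMN), the fibroblasts themselves (MEF) in 4 culture conditions, and motor neurons from embryos at E13.5 (E13.5 MN). The iMN group has 3 libraries and every other group 2. The other 6 libraries, 2 in each of 3 groups, count the 3′ ends of transcripts (3′-DGE). They cover ESC-MN grown with medium conditioned on cortical glia (CM), ESC-MN grown with medium from an empty plate (nCM), and motor neurons from embryos at E11.5 (E11.5 MN). All neurons carried a GFP reporter under the promoter of Mnx1 (Hb9) and were sorted for GFP, so Mnx1 itself is the sorting gene. The full-length libraries held 6327059 (ESC-MN library 1) to 30721412 (iPSC library 2) expected fragments, and the 3′ libraries 18919827 (CM library 1) to 39582212 (E11.5 MN library 1) counts. Levels (CPM) are counts scaled by library total and TMM factor, and the numbers after ± are standard deviations between libraries. Limits for genes at 0 counts and ratio intervals cover counting error only. The p-values measure the spread between libraries, pooled over groups, since the labels do not say if all replicates were separate cultures.

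The stated goal was to compare how similar the motor neurons of each origin are in their transcripts. All 3 in vitro groups lay much closer to E13.5 MN than to the cells they came from. On a line from the source cells (0) to E13.5 MN (1), iPSC-MN stood at 0.881 ± 0.00261 (SD, n = 2), iMN at 0.731 ± 0.0727 (SD, n = 3) and ESC-MN at 0.719 ± 0.0929 (SD, n = 2). The distance from that line was 0.454, 0.478 and 0.489 of its length. Spearman correlation across genes with E13.5 MN was 0.929 for iPSC-MN, 0.914 for iMN and 0.895 for ESC-MN, against 0.615 for ESC, 0.602 for iPSC and 0.706 for MEF in N3 medium (0.794, 0.792 and 0.846 without a filter). The 2 E13.5 libraries had a correlation of 0.937 with each other. By position iPSC-MN stood highest in every setting tried, but the order by correlation depended on the setting. Without a filter iMN stood at 0.938, iPSC-MN at 0.936 and ESC-MN at 0.922, and without E13.5 library 1 iMN at 0.905 and iPSC-MN at 0.899. Without E13.5 library 2, ESC-MN stood above iMN in correlation (0.902 and 0.899) and in position (0.721 and 0.667). Genes are not independent replicates, and no test was made of these values. In a principal component analysis, the leading components held 44.2% and 31.9% of the variance.

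**Figure D1:**
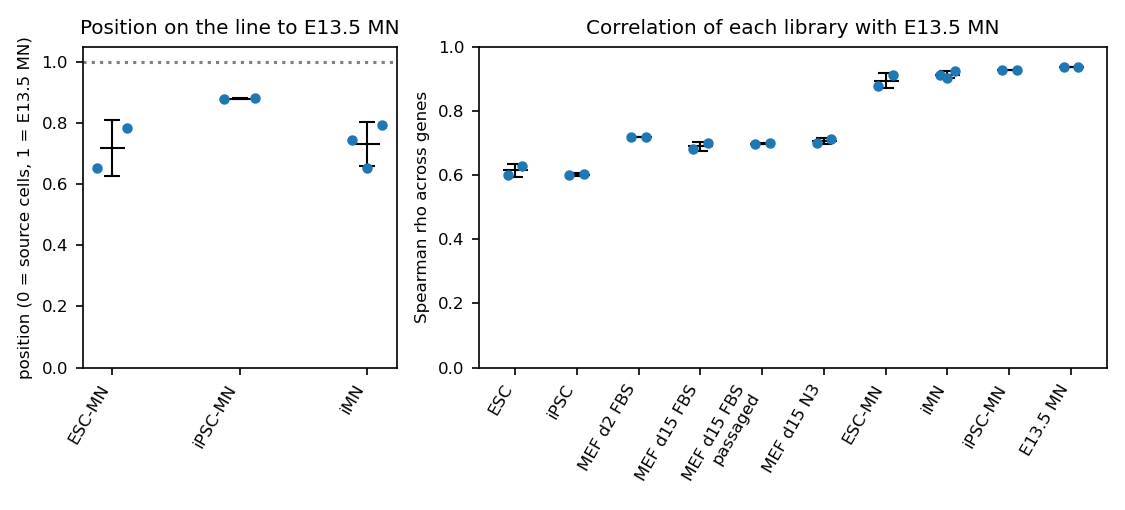
Left, the position of each derived library between its source cells (0) and E13.5 MN (1). Right, the Spearman correlation across genes of each library with the mean of E13.5 MN (for an E13.5 library, with the other one). Points are libraries, and bars are the mean and SD. The iPSC-MN libraries stand at 0.881 on average and the ESC-MN libraries at 0.719.

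Differentiation of ESC turned on the motor neuron program and turned off pluripotency genes. The labels do not state that ESC and ESC-MN came from the same line. Isl1, a transcription factor required for motor neurons, stood at 329.6 ± 36.7 against 0.453 ± 0.199 CPM (SD, n = 2), 689-fold higher (log2 fold change 9.43, SE 0.638, adjusted p = 1.4e-08). Isl1 lies on mm10 chromosome 13 from 116298281 to 116309689. Chat, which makes acetylcholine, stood at 122 ± 38.4 against 0.0593 ± 0.0839 CPM and the neuronal tubulin Tubb3 at 1475 ± 138 against 13.45 ± 0.9501 CPM. Pou5f1, a core pluripotency factor, fell 685-fold to 2.27 ± 1.94 CPM, and Nanog (chromosome 6, 122707489 to 122714633), another, fell 149-fold to 4.11 ± 0.736 CPM. Large rises included the neural zinc-finger genes Myt1 (at least 1082-fold) and St18 (at least 417-fold), the splicing factor Rbfox1 (at least 235-fold) and Gprin1 (at least 216-fold). Large falls included S100a4 (at least 234-fold), Igfbp7 (at least 142-fold), Ly6a (at least 112-fold) and Tdgf1 (3421-fold).

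In this comparison, ESC-MN against ESC, 16 of 18 measured motor neuron identity genes rose and 1 fell (16 higher and 1 lower adjusted over the list alone; median log2 fold change 6.69, camera adjusted p = 3.2e-09, and adjusted p = 0.075 with an estimated correlation). Gfra1, a receptor for the trophic factor GDNF, rose 95.6-fold, and Onecut2 stood at 172 ± 72.4 against 0.215 ± 0.136 CPM. Among pan-neuronal genes 20 of 20 rose (median 5.82, camera adjusted p = 1.2e-18, and adjusted p = 0.037 with an estimated correlation), with Map2 263-fold and Elavl4 734-fold higher. Channels and receptors rose at 16 of 23 genes, including the nicotinic receptor subunits Chrna4 (376-fold) and Chrnb2 (90.9-fold), and the NMDA receptor subunit Grin1 stood at 3.09 ± 0.336 against 5.94 ± 0.852 CPM without passing (list median 3.56, camera adjusted p = 6.2e-07, and adjusted p = 0.11 with an estimated correlation). Axon guidance genes rose at 19 of 21, with Robo2 45.7-fold and Robo1 59.0-fold higher (camera adjusted p = 3.7e-09, and adjusted p = 0.11 with an estimated correlation). All 14 measured Hox genes of paralogs 1 to 5, which mark hindbrain and cervical identity, rose (median 7.59 as fitted and 6.98 with genes at 0 counts set to their bound, camera adjusted p = 7.2e-15, and adjusted p = 0.019 with an estimated correlation), with Hoxa5 at 249 ± 49.1 against 0.805 ± 0.0364 CPM. Retinoic acid response genes, whose ligand was in the culture, rose at 9 of 11, such as Rarb (118-fold), and 1 fell (camera adjusted p = 0.011, and adjusted p = 0.11 with an estimated correlation). Without ESC-MN library 2, 5 of them rose. Cholesterol synthesis genes rose at 12 of 18 (camera adjusted p = 0.0062, and adjusted p = 0.59 with an estimated correlation), with Hsd17b7 7.68-fold higher.

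Pluripotency genes fell at 19 of 20 (median -6.52, camera adjusted p = 7.3e-23, and adjusted p = 5.9e-04 with an estimated correlation). The exception was Lin28a, an RNA-binding protein of early embryos, at 118 ± 14.7 against 151 ± 8.26 CPM (adjusted p = 0.15). All 18 measured proliferation genes fell in ESC-MN against ESC (median -3.56, camera adjusted p = 1.3e-05, and adjusted p = 0.54 with an estimated correlation), Mcm5 by 15.96-fold. Hypoxia and glycolysis genes fell at 17 of 18 (camera adjusted p = 4.1e-08, and adjusted p = 0.011 with an estimated correlation), with Pgk1 8.83-fold and Aldoa 10.9-fold lower. Fibroblast and matrix genes fell at 22 of 24 (camera adjusted p = 6.2e-07, and adjusted p = 0.46 with an estimated correlation), and interferon and antigen presentation genes at 13 of 19 (camera adjusted p = 0.0082, and adjusted p = 0.59 with an estimated correlation). The ESC libraries held Acta2 at 680.3 ± 118 CPM and Tagln at 986 ± 217 CPM beside Ifitm3 at 554 ± 156 CPM. Other cells in ESC or iPSC cultures were not tested as a source of fibroblast genes. In total 10724 of 17045 genes passed the edgeR quasi-likelihood test at an adjusted p under 0.05, 4941 higher and 5783 lower in ESC-MN.

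Differentiation of iPSC also raised motor neuron genes and lowered pluripotency genes. In iPSC-MN Isl1 stood at 361 ± 4.74 against 0.673 ± 0.252 CPM (SD, n = 2), Chat at 167 ± 6.07 CPM and Tubb3 at 2053 ± 89.5 against 13.6 ± 0.461 CPM. Pou5f1 fell 7853-fold to 0.253 ± 0.130 CPM, and Nanog fell 3019.7-fold to 0.227 ± 0.168 CPM. The neural genes Myt1 (at least 2292-fold), Nhlh2 (at least 1577-fold), Slc10a4 (at least 1487-fold), Rbfox1 (at least 1189.8-fold) and the motor neuron factor Lhx4 (at least 919-fold) were among the largest rises, and the microtubule protein Dcx reached 2311 ± 60.7 CPM. Dppa3 fell at least 435-fold and Dppa2 at least 297-fold, and Dppa5a stood at 0.115 ± 0.163 against 7317 ± 64.1 CPM.

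Of the motor neuron identity genes, 17 of 18 rose in iPSC-MN against iPSC and 1 fell (median 8.92, camera adjusted p = 3.0e-08, and adjusted p = 0.10 with an estimated correlation), with Onecut2 1835-fold and Gfra1 58.9-fold higher. Pan-neuronal genes rose at 20 of 20 (camera adjusted p = 1.2e-15, and adjusted p = 0.064 with an estimated correlation), Map2 by 243-fold and the synaptic vesicle protein Syt1 by 833-fold. Channels and receptors rose at 20 of 23 (median 5.64 as fitted and 4.36 with genes at 0 counts set to their bound; camera adjusted p = 5.5e-08, and adjusted p = 0.10 with an estimated correlation), with the AMPA receptor subunit Gria2 503-fold and Chrna4 707-fold higher. All 14 Hox genes of paralogs 1 to 5 rose (median 7.80, camera adjusted p = 1.0e-11, and adjusted p = 0.064 with an estimated correlation), with Hoxa5 at 340.2 ± 20.9 against 1.10 ± 0.0930 CPM. Pluripotency genes fell at 18 of 20 (median -9.08 as fitted and -8.89 with genes at 0 counts set to their bound; camera adjusted p = 2.3e-18, and adjusted p = 0.022 with an estimated correlation), Esrrb by 104-fold and Fbxo15 by 521-fold, while Lin28a stood at 152 ± 7.28 against 184 ± 20.97 CPM. All 18 proliferation genes fell (median -5.64, camera adjusted p = 3.8e-07, and adjusted p = 0.45 with an estimated correlation), with Pcna 21.3-fold and Aurka 78.2-fold lower. In hypoxia and glycolysis, 17 of 18 genes fell (camera adjusted p = 7.2e-06, and adjusted p = 0.064 with an estimated correlation), such as Ldha (11.0-fold), and fibroblast and matrix genes at 21 of 24 (camera adjusted p = 2.4e-04, and adjusted p = 0.64 with an estimated correlation), such as Tagln (637-fold). By the edgeR test 12366 genes passed, 5808 higher and 6558 lower in iPSC-MN, and 12165 passed with the replicate number as a block.

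The sorted iMN libraries had neuronal transcripts and far lower levels of macrophage genes than MEF, beside partly lower fibroblast genes. The iMN libraries were compared with MEF kept in N3 medium to day 15. Lhx3, 1 of the transduced factors (chromosome 2, 26200212 to 26208289), stood at 1439.9 ± 263 CPM (SD, n = 3) against 0, at least 5690.3-fold higher, and Isl1, also transduced, at 1259 ± 288 against 0.369 ± 0.0738 CPM. Vector transcripts would count toward these genes. The synaptic complexin Cplx1 rose at least 1256-fold and the potassium channel gene Kcnq2 at least 835-fold, and the neuropeptide gene Gal stood at 1435 ± 769 against 0.105 ± 0.149 CPM. Tubb3 rose 272-fold, whereas Chat reached 9.53 ± 5.30 CPM. Genes of bone-resorbing and other macrophage-like cells were among the largest falls, Atp6v0d2 by 1071-fold, Acp5 by 895-fold and Mmp9 by 274-fold. With MEF in FBS medium as the reference, Mmp9 did not pass (adjusted p = 0.13).

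Of the transduced factors, 6 of 6 rose (median 12.61 as fitted and 12.11 with genes at 0 counts set to their bound; camera adjusted p = 8.1e-15, and adjusted p = 0.0054 with an estimated correlation), with Ascl1 at 594 ± 58.8 against 0.590 ± 0.208 CPM. Motor neuron identity genes rose at 14 of 18 in iMN against MEF and 1 fell (median 5.58, camera adjusted p = 1.6e-09, and adjusted p = 0.063 with an estimated correlation), including Ret (587-fold) and Prph (139.9-fold). This list holds the transduced Mnx1, Isl1 and Lhx3. All 20 pan-neuronal genes rose (median 8.73, camera adjusted p = 1.4e-32, and adjusted p = 0.0073 with an estimated correlation), Syt1 by 365-fold. Channels and receptors rose at 22 of 23 (23 adjusted over the list alone; median 6.41 as fitted and 6.30 with genes at 0 counts set to their bound; camera adjusted p = 2.4e-20, and adjusted p = 0.0073 with an estimated correlation), with the AMPA receptor gene Gria1 60.4-fold and the sodium channel gene Scn8a 120.3-fold higher. Cholesterol synthesis genes rose at 16 of 18 (camera adjusted p = 7.9e-04, and adjusted p = 0.67 with an estimated correlation), Dhcr7 by 5.24-fold. The list did not pass against MEF in FBS medium (adjusted p = 0.077) or against all 4 MEF groups (adjusted p = 0.18). Fibroblast and matrix genes fell at 18 of 24 and 1 rose (median -2.08, camera adjusted p = 1.5e-04, and adjusted p = 0.67 with an estimated correlation). Col1a1, the main collagen (chromosome 11, 94936224 to 94953042), still stood at 678 ± 262 against 5549 ± 1186 CPM, 8.18-fold lower, and Prrx1 at 193 ± 45.4 against 407 ± 26.3 CPM (adjusted p = 0.060). All 14 microglia and macrophage genes fell (median -4.88, camera adjusted p = 2.6e-07, and adjusted p = 0.38 with an estimated correlation), Cd68 by 69.1-fold and Tyrobp by 82.2-fold. Proliferation genes fell at 15 of 18 (camera adjusted p = 0.0036, and adjusted p = 0.84 with an estimated correlation; 9 fell without iMN library 3). All 18 hypoxia and glycolysis genes fell (camera adjusted p = 1.1e-11, and adjusted p = 0.0054 with an estimated correlation), with P4ha1 11.5-fold lower. ER and amino acid stress genes fell at 11 of 15 (camera adjusted p = 0.0039, and adjusted p = 0.60 with an estimated correlation), such as Trib3 (10.9-fold). Of the motor neuron disease genes 11 of 21 rose and 1 fell (camera adjusted p = 0.12), with the kinesin gene Kif5a 74.3-fold higher and Pfn1 2.53-fold lower. Without MEF N3 library 1, 7 rose. In total 8945 genes passed the edgeR test, 4651 higher and 4294 lower in iMN.

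The embryonic reference rests on 2 libraries that differ from each other. In E13.5 library 1 Mnx1 stood at 541 CPM and in library 2 at 107 CPM, with Chat at 61.2 and 15.1 CPM. Col1a1 stood at 39.6 and 672 CPM, the Schwann cell and neural crest factor Sox10 at 0.768 and 143 CPM, the interneuron factor Pax2 at 3.48 and 86.2 CPM, and the proliferation marker Mki67 at 12.95 and 145 CPM. As a list, spinal interneuron genes had a median log2 difference of 3.79 (library 2 minus library 1), Schwann and neural crest genes 3.66, muscle genes 2.92, fibroblast and matrix genes 2.61, proliferation genes 2.61 and hedgehog response genes 2.24. For astrocyte and oligodendrocyte genes it was 1.65, for endothelial genes 0.994, for microglia and macrophage genes 0.947, for Hox genes of paralogs 9 to 13 0.356, for erythroid genes -0.34, for motor neuron identity genes -0.62 and for pan-neuronal genes -0.92. Hoxc10 stood at 47.2 and 60.5 CPM. A summed variance to mean ratio between the replicates was 147 in E13.5 MN, 101 in ESC-MN, 2.11 in iPSC-MN and 1.58 in MEF at day 2 (counting alone gives 1). Since the fit pools the spread over groups, it may understate that of E13.5 MN and ESC-MN.

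**Figure D2:**
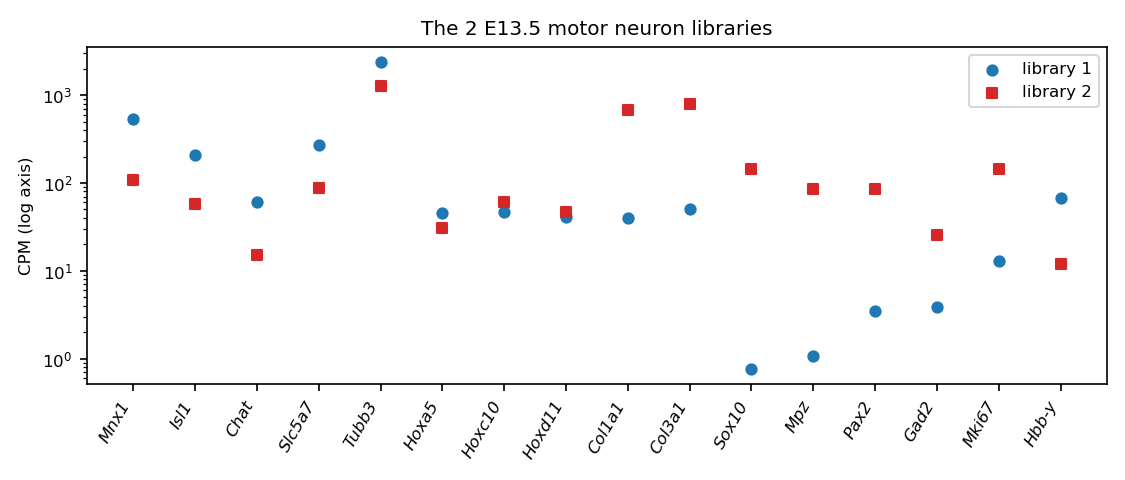
Levels of 16 genes in the 2 E13.5 motor neuron libraries, in CPM on a log axis; each point is 1 library. Motor neuron genes such as Mnx1 (541 and 107 CPM) are higher in library 1, and genes of several other cell types such as Sox10 (0.768 and 143 CPM) in library 2.

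Compared with E13.5 MN, ESC-MN had the Hox genes of an anterior position, more of several pluripotency transcripts and less of the ion channel and receptor genes. Hoxa5 (chromosome 6, 52201754 to 52204587) stood at 249 ± 49.1 against 38.3 ± 10.5 CPM (SD, n = 2), 6.49-fold higher (log2 fold change 2.70, SE 0.245, adjusted p = 1.8e-06). Hoxd11 (chromosome 2, 74679557 to 74687016) was at 0 against 44.2 ± 4.08 CPM, at least 130.3-fold lower, and Hoxc10 at 0 against 53.9 ± 9.43 CPM, at least 159-fold lower. The annotated spans of Hoxc10 and Hoxc5 overlap on 1 strand (chromosome 15, 102966796 to 102971893 and 102967443 to 103017429), so fragments of 1 may count for the other. The testis and germ cell genes Trap1a (at least 228-fold) and Sohlh2 (at least 136-fold) were among the largest rises. Hoxc13 (at least 147-fold), Hoxc12 (at least 101-fold), Col25a1 (at least 79.9-fold) and Rgs5 (at least 79.8-fold) fell among the most. Tubb3 stood at 1475 ± 138 against 1813 ± 778 CPM (adjusted p = 0.46).

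Hox genes of paralogs 1 to 5 rose in ESC-MN at 13 of 14 (14 adjusted over the list alone; median 2.92, camera adjusted p = 1.8e-18, and adjusted p = 0.014 with an estimated correlation), and all 16 of paralogs 9 to 13 fell (median -8.69 as fitted and -6.08 with genes at 0 counts set to their bound; camera adjusted p = 1.4e-21, and adjusted p = 1.2e-05 with an estimated correlation). Those of paralogs 6 to 8 went both ways, with 1 higher and 3 lower of 8 (3 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.20), Hoxb6 4.29-fold higher and Hoxc8 160.4-fold lower. Without ESC-MN library 1, 5 fell and the list passed (adjusted p = 0.030). Channels and receptors fell at 20 of 23 (median -3.62, camera adjusted p = 6.7e-14, and adjusted p = 0.025 with an estimated correlation), such as Gria1 (218-fold), the glycine receptor gene Glra2 (24.7-fold) and Kcnd2 (52.0-fold), while Chrna4 stood at 181 ± 89.4 against 99.3 ± 11.9 CPM (adjusted p = 0.077). Pan-neuronal genes fell at 9 of 20 (10 adjusted over the list alone; camera adjusted p = 0.0022, and adjusted p = 0.44 with an estimated correlation), the presynaptic genes Nrxn1 by 10.3-fold and Syn1 by 6.73-fold. Without E13.5 library 1 the list no longer passed (adjusted p = 0.36), and without library 2, 14 fell. In motor neuron identity, 6 were higher and 6 lower of 18 genes (8 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.49), Onecut1 9.10-fold higher and the acetylcholinesterase gene Ache 15.5-fold lower. Without E13.5 library 2, 3 rose, and without ESC-MN library 1, 2 rose. The list passed without E13.5 library 1 (adjusted p = 0.027) and without ESC-MN library 2 (adjusted p = 0.027). Pluripotency genes rose at 11 of 20 and 3 fell (median 3.33 as fitted and 2.38 with genes at 0 counts set to their bound; camera adjusted p = 7.8e-07, and adjusted p = 0.097 with an estimated correlation), Lin28a 79.0-fold higher and Esrrb 11.3-fold lower.

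Stress-linked and signalling lists also differed between ESC-MN and E13.5 MN. Targets of p53 rose at 11 of 15 (12 higher and 1 lower adjusted over the list alone; median 1.12, camera adjusted p = 6.5e-08, and adjusted p = 0.10 with an estimated correlation), with the cell cycle inhibitor Cdkn1a (chromosome 17, 29090976 to 29100727) at 132 ± 4.31 against 18.5 ± 0.965 CPM. ER and amino acid stress genes rose at 12 of 15 (camera adjusted p = 2.0e-07, and adjusted p = 0.16 with an estimated correlation), Sesn2 by 6.03-fold, and 7 rose without ESC-MN library 2. Hypoxia and glycolysis genes rose at 11 of 18 (camera adjusted p = 3.4e-06, and adjusted p = 0.040 with an estimated correlation) and cholesterol synthesis genes at 10 of 18 (camera adjusted p = 9.8e-06, and adjusted p = 0.34 with an estimated correlation). Retinoic acid response genes rose at 7 of 11 and 1 fell (camera adjusted p = 3.3e-05, and adjusted p = 0.025 with an estimated correlation), with Cyp26a1 15.2-fold higher. Neural progenitor genes rose at 4 of 14 (camera adjusted p = 0.022, and adjusted p = 0.38 with an estimated correlation). Hedgehog response genes fell at 6 of 12 (camera adjusted p = 0.059), and the list passed without E13.5 library 1. The list mixes target and receptor genes, so it does not show pathway activity. Imprinted genes fell at 7 of 14 and 1 rose (camera adjusted p = 0.0092, and adjusted p = 0.44 with an estimated correlation), and Meg3 (chromosome 12, 109541001 to 109571726) stood at 456 ± 69.0 against 5960.4 ± 39.2 CPM, 13.1-fold lower.

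Markers of other cell types were lower in ESC-MN than in E13.5 MN, several of them together with the difference between the E13.5 libraries. Spinal interneuron genes fell at 14 of 17 (camera adjusted p = 0.0069, and adjusted p = 0.53 with an estimated correlation), 5 of them without E13.5 library 2 (list adjusted p = 0.13) and 7 without ESC-MN library 2. Fibroblast and matrix genes fell at 22 of 24 (camera adjusted p = 3.8e-10, and adjusted p = 0.32 with an estimated correlation), and 17 of these 22 stayed lower without E13.5 library 2. Schwann and neural crest genes fell at 7 of 12 (camera adjusted p = 0.16), 3 without E13.5 library 2 and 4 without ESC-MN library 2. The list passed without E13.5 library 1 (adjusted p = 2.4e-07). Endothelial genes fell at 9 of 12 (camera adjusted p = 0.0039, and adjusted p = 0.32 with an estimated correlation), erythroid genes at 6 of 8 (camera adjusted p = 1.6e-04, and adjusted p = 0.13 with an estimated correlation), and microglia and macrophage genes at 10 of 14 (camera adjusted p = 8.2e-04, and adjusted p = 0.47 with an estimated correlation; 5 of the 10 without E13.5 library 2). The hemoglobin genes are near copies of each other, so their individual levels are uncertain. By the edgeR test 5997 genes passed, 2106 higher and 3891 lower in ESC-MN. Without ESC-MN library 2, 3836 passed, and with only these 2 groups in the fit 1513. In this comparison Isl1 stood at 329.6 ± 36.7 against 133 ± 107 CPM (adjusted p = 0.018) and Chat at 122 ± 38.4 against 38.1 ± 32.6 CPM (adjusted p = 0.035). Neither passed without E13.5 library 2 or without ESC-MN library 1, nor did Chat without ESC-MN library 2.

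**Figure D3:**
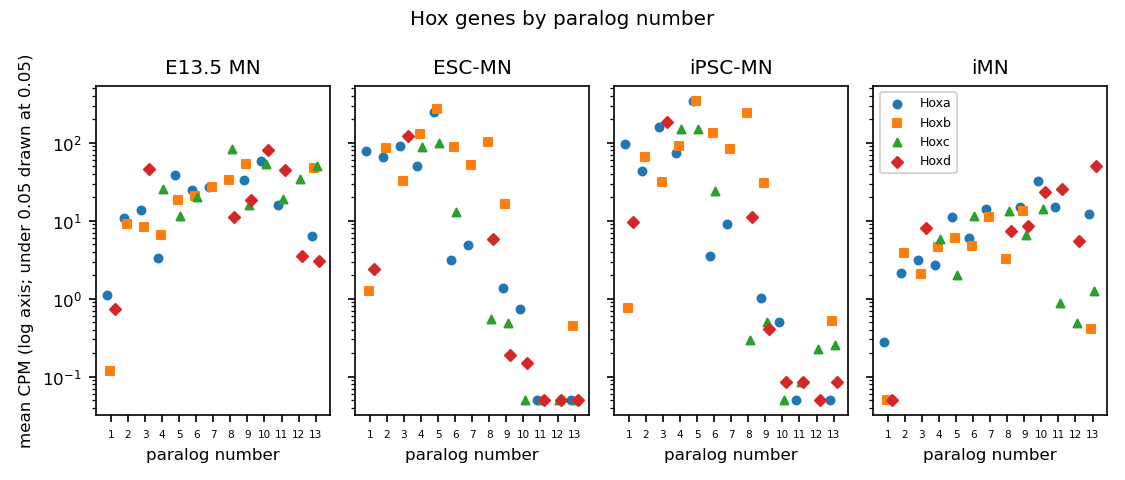
Mean levels of Hox genes in E13.5 MN, ESC-MN, iPSC-MN and iMN by paralog number, in CPM on a log axis; symbols give the cluster, and means under 0.05 are drawn at 0.05. Hoxa5 stands at 249 CPM in ESC-MN and 38.3 CPM in E13.5 MN, and Hoxc10 at 0 CPM in ESC-MN and 53.9 CPM in E13.5 MN.

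In iPSC-MN, too, anterior Hox genes were higher and posterior Hox, channel and receptor genes lower than in E13.5 MN. Hoxa5 was 8.88-fold higher, at 340.2 ± 20.9 CPM (SD, n = 2), Hoxa1 84.3-fold higher and Hoxc10 at least 213-fold lower. Lin28a stood at 152 ± 7.28 against 1.48 ± 0.0825 CPM, 102-fold higher. The collagen gene Col9a1 (at least 129-fold), Hba-a1 (at least 89.4-fold) and Hoxa11 (at least 62.8-fold) fell among the most.

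Of the Hox genes in iPSC-MN against E13.5 MN, 13 of 14 of paralogs 1 to 5 rose (14 adjusted over the list alone; median 3.34, camera adjusted p = 2.6e-26, and adjusted p = 0.0046 with an estimated correlation) and 15 of 16 of paralogs 9 to 13 fell (median -7.16 as fitted and -6.50 with genes at 0 counts set to their bound; camera adjusted p = 2.1e-29, and adjusted p = 2.5e-06 with an estimated correlation). Hoxb9 was the exception, at 30.4 ± 3.77 against 54.2 ± 28.0 CPM. Motor neuron identity genes rose at 9 of 18 and fell at 4 (11 higher and 4 lower adjusted over the list alone; median 1.33, camera adjusted p = 0.0091, and adjusted p = 0.44 with an estimated correlation), Onecut2 8.69-fold higher and Etv4 6.64-fold lower. Without E13.5 library 2 the list did not pass (adjusted p = 0.34). Without E13.5 library 1, 2 fell. Without iPSC-MN library 1, 5 rose and 2 fell, and without iPSC-MN library 2, 3 rose and 2 fell. Isl1 (2.71-fold higher, adjusted p = 0.014) and Chat (4.37-fold higher, adjusted p = 0.015) did not pass without either iPSC-MN library. Channels and receptors fell at 14 of 23 (15 adjusted over the list alone; median -2.73, camera adjusted p = 2.1e-09, and adjusted p = 0.051 with an estimated correlation), Gria1 by 107-fold and Kcnd2 by 20.6-fold. Targets of p53 rose at 10 of 15 (camera adjusted p = 1.6e-08, and adjusted p = 0.091 with an estimated correlation), with Cdkn1a 8.52-fold and Eda2r 20.5-fold higher. In hypoxia and glycolysis, 14 of 18 genes rose and 1 fell (camera adjusted p = 1.6e-08, and adjusted p = 0.014 with an estimated correlation), Egln3 by 5.67-fold, and cholesterol synthesis genes rose at 15 of 18 (camera adjusted p = 7.8e-11, and adjusted p = 0.15 with an estimated correlation). Without iPSC-MN library 2 these 3 lists had 6, 9 and 9 higher genes. Retinoic acid response genes rose at 8 of 11 (camera adjusted p = 1.9e-06, and adjusted p = 0.014 with an estimated correlation).

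Cell type lists that differ between the E13.5 libraries were lower in iPSC-MN. Proliferation genes fell at 11 of 18 (13 adjusted over the list alone; camera adjusted p = 0.024, and adjusted p = 0.62 with an estimated correlation), and none passed without E13.5 library 2 or without either iPSC-MN library. Spinal interneuron genes fell at 14 of 17 (camera adjusted p = 5.6e-04, and adjusted p = 0.45 with an estimated correlation), 7 of them without E13.5 library 2 and 4 without iPSC-MN library 2. Fibroblast and matrix genes fell at 22 of 24 (camera adjusted p = 5.9e-11, and adjusted p = 0.26 with an estimated correlation), with 12 and 13 lower in those settings. Astrocyte and oligodendrocyte genes fell at 8 of 15 and 1 rose (camera adjusted p = 0.013, and adjusted p = 0.56 with an estimated correlation), and muscle genes fell at 10 of 12 (camera adjusted p = 0.0073, and adjusted p = 0.56 with an estimated correlation). Neither list passed without E13.5 library 2 (adjusted p = 0.35 and 0.34; 5 genes lower in each), and 4 genes of each fell without iPSC-MN library 2. In total 4424 genes passed the edgeR test, 1507 higher and 2917 lower in iPSC-MN. Without iPSC-MN library 1, 2489 passed, without library 2, 1878, and with only these 2 groups 844.

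In iMN, interferon, NF-kB, fibroblast and p53 target genes were higher than in E13.5 MN, and most Hox genes lower. The cyclin-dependent kinase inhibitors Cdkn2b (24.5 ± 4.67 CPM against 0; at least 145-fold higher; SD, n = 3) and Cdkn2a (chromosome 4, 89274471 to 89294653; 27.8 ± 9.37 against 0.0512 ± 0.0724 CPM) were among the largest rises. So were the acute phase genes Lcn2 (88.3 ± 127 CPM) and Saa3 (24.4 ± 20.1 CPM) and the astrocyte filament Gfap (76.6 ± 78.9 CPM), whose levels varied widely between iMN libraries. Pax8 (at least 75.9-fold) and the hemoglobin genes Hbb-y (at least 162-fold) and Hba-a2 (at least 57.8-fold) were among the largest falls. Chat stood at 9.53 ± 5.30 against 38.1 ± 32.6 CPM, 3.93-fold lower (adjusted p = 0.012), and did not pass without E13.5 library 1. Isl1, a transduced gene, stood at 1259 ± 288 against 133 ± 107 CPM.

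All 19 interferon and antigen presentation genes rose in iMN (median 4.21, camera adjusted p = 4.7e-19, and adjusted p = 0.062 with an estimated correlation), with Ifi27 105-fold, Ifitm3 47.1-fold and Stat1 5.84-fold higher. NF-kB pathway genes rose at 16 of 29 (18 adjusted over the list alone; camera adjusted p = 3.3e-08, and adjusted p = 0.026 with an estimated correlation), Bcl3 by 76.1-fold and Csf1 by 5.82-fold. Fibroblast and matrix genes rose at 12 of 24 (camera adjusted p = 1.5e-08, and adjusted p = 0.26 with an estimated correlation), Loxl1 by 20.6-fold and Thy1 by 17.2-fold, and 23 rose without E13.5 library 2. Targets of p53 rose at 9 of 15 (camera adjusted p = 2.9e-11, and adjusted p = 0.062 with an estimated correlation), Cdkn1a by 16.9-fold. Immediate early genes rose at 5 of 13 (9 adjusted over the list alone; camera adjusted p = 0.0011, and adjusted p = 0.48 with an estimated correlation), Arc by 9.94-fold, and 9 rose without iMN library 3. Transduced factors were 5 higher and 1 lower of 6 (camera adjusted p = 8.6e-12, and adjusted p = 0.014 with an estimated correlation). In motor neuron identity, 5 were higher and 8 lower of 18 genes (5 higher and 9 lower adjusted over the list alone; median -1.19, camera adjusted p = 0.073), with Gfra1 3.97-fold higher and Nkx6-1 131-fold and the choline transporter Slc5a7 11.6-fold lower. The list passed without E13.5 library 2. Pan-neuronal genes fell at 8 of 20 and 1 rose (camera adjusted p = 0.035, and adjusted p = 0.60 with an estimated correlation), Dcx by 3.62-fold. That call was lost without E13.5 library 1, iMN library 1 (adjusted p = 0.067; 5 lower) and iMN library 2 (0.11; 4 lower). Channels and receptors were 2 higher and 7 lower of 23 (camera adjusted p = 0.035, and adjusted p = 0.48 with an estimated correlation).

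Hox genes of paralogs 1 to 5 fell in iMN at 11 of 14 (median -2.09 as fitted and -1.97 with genes at 0 counts set to their bound; camera adjusted p = 5.3e-08, and adjusted p = 0.087 with an estimated correlation), and those of paralogs 9 to 13 at 11 of 16, with 1 higher (median -1.23, camera adjusted p = 1.1e-04, and adjusted p = 0.014 with an estimated correlation). Hoxb13 fell 124-fold and Hoxd13 rose 16.9-fold, and 7 of paralogs 9 to 13 fell without E13.5 library 2. Paralogs 6 to 8 fell at 6 of 8 (camera adjusted p = 9.7e-04, and adjusted p = 0.43 with an estimated correlation). All 8 erythroid genes fell (camera adjusted p = 1.2e-08, and adjusted p = 0.026 with an estimated correlation), as did 9 of 12 endothelial genes (camera adjusted p = 3.3e-05, and adjusted p = 0.15 with an estimated correlation; 5 without E13.5 library 2), such as Kdr (5.66-fold), and 9 of 12 Schwann and neural crest genes (camera adjusted p = 0.0094, and adjusted p = 0.48 with an estimated correlation). Spinal interneuron genes fell at 12 of 17 (camera adjusted p = 0.0014, and adjusted p = 0.48 with an estimated correlation), Lhx1 by 57.5-fold. Without E13.5 library 2, 7 fell and the list did not pass (adjusted p = 0.096). By the edgeR test 4479 genes passed, 2187 higher and 2292 lower in iMN, and 1114 with only these 2 groups in the fit.

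The 3 in vitro groups shared 170 genes higher and 617 genes lower than in E13.5 MN, where independent lists would share 23.9 and 89.5. Among the shared higher genes were 8 p53 targets (Cdkn1a, Trp53inp1, Pmaip1, Ccng1, Phlda3, Zmat3, Eda2r and Aen) and the stress genes Trib3, Sesn2 and Mthfd2. Among the shared lower genes were 10 Hox genes of paralogs 9 to 13, 10 spinal interneuron genes, and 6 each of the erythroid, endothelial, Schwann and muscle lists. Since all comparisons use the same 2 E13.5 libraries, groups without a true change were simulated against them, which shared 0 genes in 20 draws. Having no true change to call, they cannot show what part of the excess comes from the shared controls. The log2 fold changes correlated across genes at 0.814 between ESC-MN and iPSC-MN (simulated 0.429), at 0.149 between ESC-MN and iMN (simulated 0.471) and at 0.143 between iPSC-MN and iMN (simulated 0.516), with covariances of 2.64, 0.444 and 0.363 (simulated 0.166, 0.163 and 0.164). The groups shared fewer genes without either iPSC-MN library. Without E13.5 library 2 they shared 385 higher genes, and without E13.5 library 1, 1060 lower ones.

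**Figure D4:**
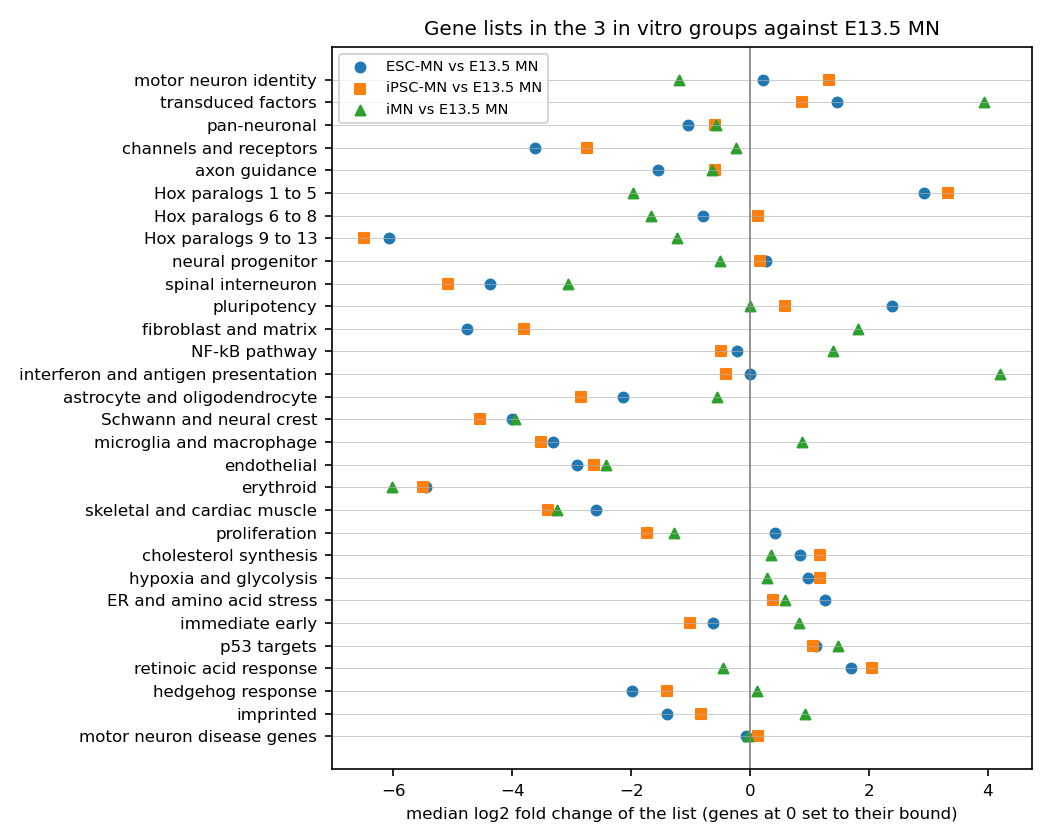
Median log2 fold change of each of the 30 gene lists against E13.5 MN, with genes at 0 counts set to their bound; symbols give the in vitro group. Hox genes of paralogs 1 to 5 stand at 2.92 in ESC-MN, 3.34 in iPSC-MN and -1.97 in iMN.

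Between the pluripotent sources, iPSC-MN had lower pluripotency, proliferation and immediate early genes than ESC-MN and more of some neuronal genes. Nanog stood at 0.227 ± 0.168 against 4.11 ± 0.736 CPM (SD, n = 2), 21.1-fold lower (adjusted p = 2.1e-04), and the immediate early gene Fos at 4.71 ± 0.633 against 41.1 ± 18.5 CPM, 8.66-fold lower. The imprinted Meg3 was 6.47-fold and Grb10 16.1-fold higher. The Y-linked genes Ddx3y (at least 79.7-fold), Uty (at least 64.5-fold) and Kdm5d (at least 35.2-fold) rose from 0 counts in ESC-MN. The neural factor Neurod4 fell 27.0-fold, and Stra8 33.6-fold.

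Pluripotency genes fell at 8 of 20 (1 higher and 13 lower adjusted over the list alone; median -2.34 as fitted and -2.05 with genes at 0 counts set to their bound; camera adjusted p = 4.3e-09, and adjusted p = 0.21 with an estimated correlation), proliferation genes at 11 of 18 (16 adjusted over the list alone; camera adjusted p = 5.7e-15, and adjusted p = 0.40 with an estimated correlation) and immediate early genes at 4 of 13 (6 adjusted over the list alone; camera adjusted p = 1.7e-08, and adjusted p = 0.40 with an estimated correlation). Motor neuron identity genes rose at 6 of 18 (camera adjusted p = 0.0065, and adjusted p = 0.61 with an estimated correlation), Ret by 4.26-fold, and pan-neuronal genes at 4 of 20 (8 adjusted over the list alone; camera adjusted p = 2.5e-05, and adjusted p = 0.58 with an estimated correlation), Syn1 by 3.91-fold. Channels and receptors rose at 3 of 23 (11 adjusted over the list alone; camera adjusted p = 2.2e-05, and adjusted p = 0.40 with an estimated correlation), and imprinted genes at 2 of 14 (camera adjusted p = 0.20). By the edgeR test 954 genes differed, 607 higher and 347 lower in iPSC-MN. This rested on single libraries: 4179 passed without ESC-MN library 1, 38 without ESC-MN library 2, 66 without iPSC-MN library 1 and 43 without iPSC-MN library 2, and 21 of the 30 named genes that passed lost their call in at least 1 of these. Without ESC-MN library 2, 0 motor neuron identity, 0 pan-neuronal and 0 proliferation genes and 1 pluripotency gene passed, and the motor neuron identity list did not (adjusted p = 0.12). With either iPSC-MN library left out at most 1 gene of each of these lists passed. Immediate early genes fell at 8 and pan-neuronal genes rose at 10 without ESC-MN library 1. With only these groups in the fit 0 genes passed. With title style as a term 3331 passed, and by DESeq2 2206.

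Against ESC-MN, iMN had more fibroblast, interferon and posterior Hox transcripts and fewer anterior Hox transcripts. Prrx1 stood at 193 ± 45.4 CPM (SD, n = 3) against 0, at least 569-fold higher, and Serpina3n was at least 589.7-fold higher. Stra8 (at least 189-fold) and Trap1a (at least 156-fold) fell to 0. All 24 fibroblast and matrix genes rose (camera adjusted p = 6.1e-16, and adjusted p = 0.15 with an estimated correlation), as did 18 of 19 interferon genes (camera adjusted p = 1.3e-07, and adjusted p = 0.30 with an estimated correlation) and 13 of 14 microglia and macrophage genes (camera adjusted p = 0.0059, and adjusted p = 0.67 with an estimated correlation; 8 without ESC-MN library 2). All 14 Hox genes of paralogs 1 to 5 fell (camera adjusted p = 1.2e-26, and adjusted p = 0.0020 with an estimated correlation), Hoxa5 by 22.2-fold, and 14 of 16 of paralogs 9 to 13 rose (camera adjusted p = 2.4e-08, and adjusted p = 0.0015 with an estimated correlation), Hoxa10 by 44.4-fold. Channels and receptors were 18 higher and 2 lower of 23 (camera adjusted p = 3.9e-06, and adjusted p = 0.15 with an estimated correlation), Gria1 485-fold higher and Chrna4 15.2-fold lower. Retinoic acid response genes fell at 7 of 11 (camera adjusted p = 9.5e-06, and adjusted p = 0.0040 with an estimated correlation). Motor neuron identity genes, transduced ones included, were 6 higher and 9 lower (camera adjusted p = 0.13), and the list passed without ESC-MN library 2. In total 8246 genes passed the edgeR test, 4806 higher and 3440 lower in iMN, and 4935 with only these groups in the fit.

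Undifferentiated iPSC and ESC differed at 1 gene by the edgeR test, the Y-linked Eif2s3y, at 28.9 ± 0.0341 against 3.22 ± 0.146 CPM (SD, n = 2; 8.94-fold; adjusted p = 0.036). Leaving out any 1 of the 4 libraries left 0 genes, as did the replicate number as a block. DESeq2 and edgeR without a filter each gave 2, and edgeR with only these groups 3. At an unadjusted p under 0.05 there were 299 genes. Muscle genes had a camera call (camera adjusted p = 0.024, and adjusted p = 0.96 with an estimated correlation) with 0 genes passing, lost without ESC library 1 (adjusted p = 0.74) and without iPSC library 2 (adjusted p = 0.20).

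In fibroblast cultures at day 15, the largest rises in N3 against FBS medium included the osteoclast or macrophage genes Mmp9, at 819 ± 76.2 against 8.01 ± 1.42 CPM (SD, n = 2; 102-fold), Ocstamp (100.1-fold) and Marco (282-fold). Thy1 fell 11.3-fold and Actg2 30.9-fold. Fibroblast and matrix genes fell at 4 of 24 (camera adjusted p = 0.23), hypoxia and glycolysis genes rose at 3 of 18 (5 adjusted over the list alone; camera adjusted p = 0.0044, and adjusted p = 0.57 with an estimated correlation), and 0 microglia and macrophage genes of the list passed (median -0.52, camera adjusted p = 0.46). Without any 1 of the 4 libraries, 1 fibroblast gene and 0 hypoxia genes passed. By the edgeR test 950 genes passed, 517 higher and 433 lower in N3 medium. The count was 1794 with title style as a term, 1475 by DESeq2, 4792 with only these groups, and 804 with replicate number as a block. It fell with any 1 library left out.

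Passaged fibroblasts differed from unpassaged ones in 64 genes (21 higher and 43 lower), among them the cartilage collagen gene Col10a1 at 217 ± 13.9 against 17.1 ± 1.75 CPM (SD, n = 2; 12.7-fold higher) and the keratin gene Krt14 (9.79-fold lower). Hypoxia and glycolysis genes fell at 4 of 18 (13 adjusted over the list alone; camera adjusted p = 2.1e-32, and adjusted p = 7.5e-05 with an estimated correlation). With 1 library left out 1 or 2 fell. Astrocyte and oligodendrocyte genes (camera adjusted p = 6.6e-04, and adjusted p = 0.70 with an estimated correlation) and proliferation genes (camera adjusted p = 1.8e-10, and adjusted p = 0.57 with an estimated correlation) had lower calls with 0 genes passing. Without 1 library the count was 15 or 18 (unpassaged libraries 1 and 2) and 3 or 10 (passaged libraries 1 and 2), and of 12 named genes that passed 10 lost their call, Krt14 without either passaged library. It was 115 without a filter, 268 with title style, 209 by DESeq2, 2369 with only these groups and 43 with the block.

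From day 2 to day 15 in FBS medium, fibroblast cultures gained macrophage transcripts and lost Aldh1a3 (159.9-fold lower) and Il6 (15.2-fold). Whether the macrophage transcripts came from fibroblasts or other cells was not tested. The prostaglandin-degrading enzyme gene Hpgd rose to 168 ± 28.1 CPM (SD, n = 2), 301-fold higher. Microglia and macrophage genes rose at 11 of 14 (14 adjusted over the list alone; camera adjusted p = 0.021, and adjusted p = 0.99 with an estimated correlation), C1qc by 11.0-fold, and NF-kB pathway genes fell at 14 of 29 with 2 higher (camera adjusted p = 0.040, and adjusted p = 0.99 with an estimated correlation), Csf1 by 9.56-fold. Cholesterol synthesis genes fell at 9 of 18 (camera adjusted p = 0.021, and adjusted p = 0.99 with an estimated correlation), Ldlr by 10.4-fold, and 7 of 16 Hox genes of paralogs 9 to 13 rose (camera adjusted p = 0.37). Macrophage genes rose at 7 without day 15 library 1, 5 without day 2 library 1 and 6 without day 2 library 2. NF-kB genes fell at 7 without day 15 library 1 and at 9 without any other library, with the list lost without day 15 library 2 (adjusted p = 0.062), and 4 Hox genes rose without day 2 library 2. In total 6983 genes passed the edgeR test, 3371 higher and 3612 lower at day 15, 4453 with title style and 6606 with the block. Fewer passed with any 1 library left out.

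Medium conditioned on glia gave 0 genes that passed the edgeR test in ESC-MN, where 888 genes had an unadjusted p under 0.05. DESeq2 called 203 genes (129 higher and 74 lower) and edgeR without a filter 1. Chat stood at 87.3 ± 86.1 against 136 ± 3.43 CPM in CM against nCM (SD, n = 2), Isl1 at 294 ± 79.8 against 335 ± 85.4 CPM, Map2 at 245 ± 63.9 against 429.6 ± 2.90 CPM, the immediate early gene Jun at 249 ± 26.3 against 504 ± 27.1 CPM, Onecut2 at 246 ± 119 against 466 ± 65.5 CPM and the hypoxia-induced Ndrg1 at 166 ± 21.2 against 88.4 ± 35.6 CPM (adjusted p 0.70 or more). In CM library 1 Chat stood at 26.4 CPM and in library 2 at 148 CPM, and Meg3 at 195 and 1059 CPM. Lists were lower in CM for motor neuron identity (median -0.58, camera adjusted p = 2.6e-04, and adjusted p = 0.75 with an estimated correlation), pan-neuronal (-0.48, camera adjusted p = 3.4e-04, and adjusted p = 0.75 with an estimated correlation), axon guidance (-0.52, camera adjusted p = 3.1e-04, and adjusted p = 0.75 with an estimated correlation) and immediate early genes (-0.78, camera adjusted p = 0.0031, and adjusted p = 0.75 with an estimated correlation). Hypoxia and glycolysis genes were higher as a list (0.48, camera adjusted p = 0.0022, and adjusted p = 0.75 with an estimated correlation). Without CM library 1 these 5 lists had adjusted p of 0.52, 0.64, 0.37, 0.37 and 0.64, and the hypoxia median was -0.04. Without nCM library 2 they had 0.12, 0.43, 0.055, 0.097 and 0.43, and the immediate early list was also lost without nCM library 1 (0.11). Adjusted over the list alone, 1 motor neuron identity gene and 1 immediate early gene were lower. In simulated data with the spread pooled over the 3′ libraries, 2% of 2-fold and 47% of 4-fold changes were recovered among genes at 10 CPM or more.

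Against E11.5 MN, ESC-MN in control medium had little of the posterior Hox transcripts, less of the pan-neuronal genes and clear pluripotency, interferon and hypoxia transcripts. Hoxc10 was at 0 against 217 ± 12.1 CPM (SD, n = 2), at least 1939.9-fold lower (adjusted p = 3.4e-04), Hoxd11 at least 717-fold lower, and Hoxa9 18.3-fold lower. Fbxo15, a pluripotency gene, stood at 20.0 ± 6.71 CPM against 0, at least 193-fold higher, and the pluripotency-linked Klf4 at 117 ± 36.3 against 7.25 ± 1.97 CPM. The annexin gene Anxa1 (at least 361-fold) and Vax2 (at least 190.4-fold) were among the largest rises. The embryonic globin Hbb-y stood at 0.0153 ± 0.0216 against 274 ± 57.4 CPM.

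Hox genes of paralogs 9 to 13 fell in nCM ESC-MN at 10 of 15 (15 adjusted over the list alone; camera adjusted p = 6.3e-21, and adjusted p = 0.19 with an estimated correlation), with 6 lower without nCM library 1 and 6 without E11.5 library 1. Hox genes of paralogs 1 to 5 had 1 higher of 15 (3 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.049, and adjusted p = 0.80 with an estimated correlation). Pluripotency genes rose at 10 of 18 (13 adjusted over the list alone; median 7.48 as fitted and 4.66 with genes at 0 counts set to their bound; camera adjusted p = 4.6e-14, and adjusted p = 0.19 with an estimated correlation), Dnmt3l by 1117-fold. Interferon and antigen presentation genes rose at 5 of 17 (10 adjusted over the list alone; camera adjusted p = 1.2e-10, and adjusted p = 0.19 with an estimated correlation), such as H2-K1 (10.7-fold) and Bst2 (57.7-fold). In hypoxia and glycolysis, 6 of 16 genes rose (9 adjusted over the list alone; camera adjusted p = 8.4e-12, and adjusted p = 0.28 with an estimated correlation), the glucose transporter Slc2a1 by 10.3-fold. Targets of p53 rose at 4 of 14 (8 adjusted over the list alone; camera adjusted p = 1.3e-08, and adjusted p = 0.23 with an estimated correlation), Cdkn1a by 11.3-fold and Phlda3 by 10.7-fold, and 2 rose without either nCM library. Pan-neuronal genes fell at 9 of 18 (14 adjusted over the list alone; camera adjusted p = 4.6e-11, and adjusted p = 0.29 with an estimated correlation), Stmn2 by 2.92-fold, but at 0 without nCM library 1, at 1 without nCM library 2 and at 5 without E11.5 library 2. In motor neuron identity, 1 was higher and 2 were lower of 20 genes (1 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.11), with Foxp1, which marks limb-innervating columns, 5.49-fold lower. The progenitor factor Olig2 stood at 41.5 ± 3.57 against 3.19 ± 0.178 CPM, and neural progenitor genes were 1 higher and 2 lower of 13 (camera adjusted p = 0.82). By the edgeR test 584 genes passed, 393 higher and 191 lower in nCM ESC-MN. Without nCM library 1, 349 passed (226 and 123), without nCM library 2, 373 (286 and 87), without E11.5 library 2, 367 (288 and 79), by DESeq2 1632, and with the block 697. Of the 40 named genes that passed, 16 lost their call without 1 of the libraries, including Foxp1 and Stmn2 without either nCM library and Olig2 without nCM library 1.

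In conditioned medium, posterior Hox, pan-neuronal and axon guidance genes were lower than in E11.5 MN, and pluripotency and hypoxia genes higher. Hoxc10 was at 0 (at least 1656-fold lower) and the T-cell and neuronal factor Bcl11b at 0 against 93.0 ± 17.0 CPM (SD, n = 2; at least 710.1-fold lower). Pan-neuronal genes fell at 12 of 18 (16 adjusted over the list alone; camera adjusted p = 6.9e-16, and adjusted p = 0.20 with an estimated correlation), axon guidance genes at 7 of 20 with 1 higher (camera adjusted p = 8.9e-07, and adjusted p = 0.17 with an estimated correlation), and Hox genes of paralogs 9 to 13 at 10 of 15 (camera adjusted p = 1.0e-16, and adjusted p = 0.17 with an estimated correlation). Motor neuron identity genes fell at 5 (1 higher and 8 lower adjusted over the list alone; camera adjusted p = 1.1e-04, and adjusted p = 0.41 with an estimated correlation). Pluripotency genes rose at 11 of 18 (camera adjusted p = 3.6e-15, and adjusted p = 0.17 with an estimated correlation) and hypoxia and glycolysis genes at 10 of 16 (15 adjusted over the list alone; camera adjusted p = 3.2e-15, and adjusted p = 0.20 with an estimated correlation), Ndrg1 by 24.4-fold. Without CM library 1, 3 axon guidance genes fell, and 6 pluripotency and 5 hypoxia genes rose. In total 966 genes passed the edgeR test, 583 higher and 383 lower in CM ESC-MN, 428 without CM library 1 (271 and 157), 1504 without CM library 2 (721 and 783), 599 without E11.5 library 2 (404 and 195), 2162 by DESeq2 and 1375 with the block. The change from nCM to CM correlated across 13757 genes with the change from nCM to E11.5 MN at 0.436, where unchanged groups sharing the nCM libraries gave 0.498, with covariances of 2.85 and 1.21. Without nCM library 1 or 2 the correlation rose to 0.612 and 0.523 (covariances 7.34 and 5.08), settings for which no unchanged groups were simulated.

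**Figure D5:**
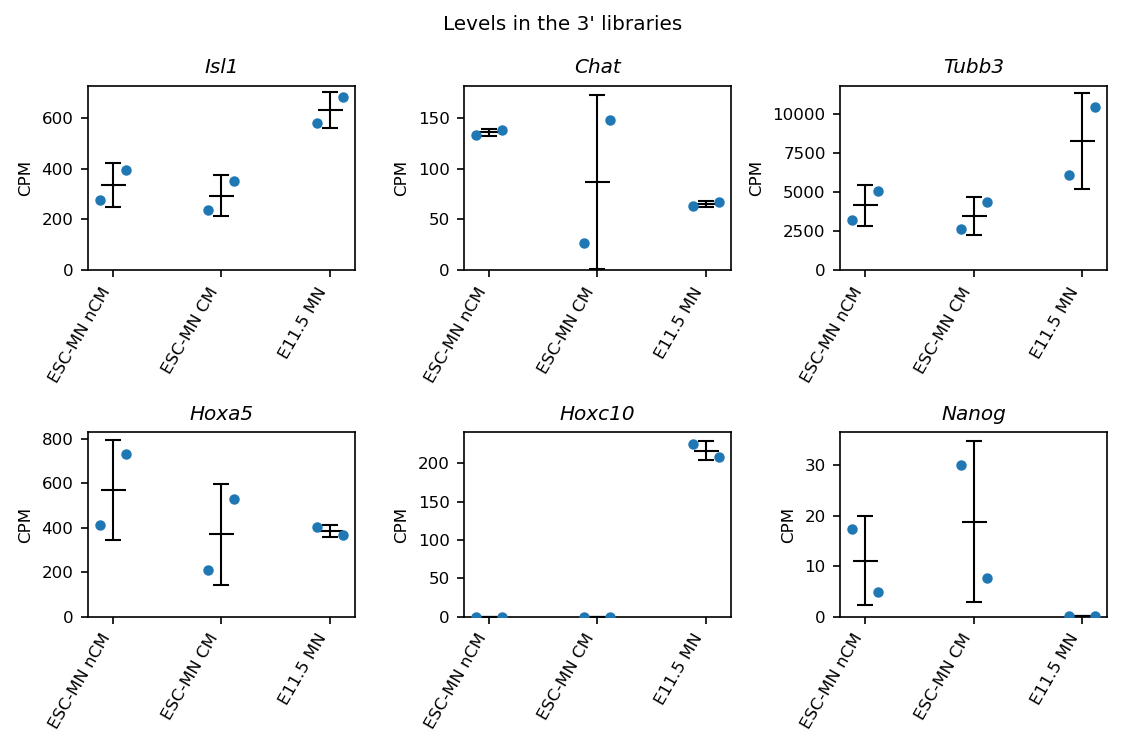
Levels of 6 genes in the 3′ libraries of ESC-MN in control (nCM) and glia-conditioned (CM) medium and of E11.5 MN, in CPM; points are libraries, bars the mean and SD. Hoxc10 is at 0 in both ESC-MN groups and at 217 CPM in E11.5 MN, and Chat in CM stands at 26.4 and 148 CPM.

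The gap between ESC-MN and embryonic motor neurons was compared across the library sets, which share no library but differ in embryonic age, in method and, by the labels, in retinoic acid dose (0.1 and 1 µM). Over 12720 genes the log2 fold changes of ESC-MN against E13.5 MN and of nCM ESC-MN against E11.5 MN correlated at 0.365 (Pearson) and 0.315 (Spearman). Of 333 genes that passed in both, 146 were higher and 129 lower in ESC-MN both times, where independent lists would share 54.5 and 41.9, and 58 went opposite ways. Without nCM library 1, nCM library 2 or E11.5 library 2, 195, 211 and 221 passed in both, with 86, 101 and 117 higher and 72, 64 and 65 lower. With 1 library left out 30 to 84 went opposite ways.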

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

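All tests in this part were chosen only after the result was seen, except the test of fibroblasts in the iMN libraries as the source of fibroblast genes and the planned comparison of the lines.

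The change from ESC to ESC-MN differed from that from iPSC to iPSC-MN at 26 genes (15 more positive and 11 more negative in ESC) by an edgeR test of the difference itself (Benjamini-Hochberg adjusted p under 0.05). In log2 units, ESC minus iPSC line, the difference was 4.34 for Nanog, 7.29 for Dppa2, 3.69 for Fos, 4.72 for Fosb and 3.17 for Egr1. It was -4.64 for Eif2s3y, -10.00 for Ddx3y and -10.02 for Kdm5d, Y-linked genes; those of Dppa2, Ddx3y and Kdm5d rest on a group at 0 counts and that of Eif2s3y on ESC-MN counts of 1 and 2, so these 4 depend on the prior count and give no size. The labels do not state that ESC-MN came from the line of the ESC libraries, and a difference between such lines would enter this test. Fos stood at 41.1 ± 18.5 CPM in ESC-MN against 18.3 ± 1.25 in ESC, and at 4.71 ± 0.633 in iPSC-MN against 27.3 ± 1.39 in iPSC (SD, n = 2). List medians of the difference were 2.35 for pluripotency (camera adjusted p = 2.4e-09), 2.35 for proliferation (2.1e-14), 1.24 for immediate early (2.0e-09), 0.98 for ER and amino acid stress (0.00024), -0.85 for pan-neuronal (0.0022), -1.34 for channels and receptors (0.0039) and -0.29 for imprinted genes (0.043). With an estimated correlation the adjusted p was 0.20, 0.42, 0.42, 0.74, 0.87, 0.74 and 0.87. Without ESC-MN library 1, 2206 genes passed, without ESC-MN library 2, 4, without ESC library 1, 9, and ESC library 2, 2, without iPSC-MN library 1, 3, and library 2, 1, and without either iPSC library 3. It was 77 without a filter, 1032 with title style, 132 with only these 4 groups and 391 by DESeq2.

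Pluripotency genes were higher in ESC-MN than in iPSC-MN, with 8 of 20 passing. Depth of the iPSC-MN libraries is argued against, since 70.0% of all 20 (14 genes; 2 were higher) were lower than in ESC-MN beyond counting error (binomial test of summed counts, p under 0.05). Of 25 genes chosen as abundant in ESC and nearly absent from E13.5 MN and iPSC-MN, 88.0% stood in ESC-MN within 4-fold of a median 0.441% of their ESC level (0.191% in library 1, 0.546% in library 2; 1.07% for the pluripotency list, quartiles 0.388% and 2.17%), as a small share of undifferentiated cells would need, with Pou5f1 at 2.27 CPM against 1619.9 CPM in ESC. Such cells may therefore contribute, although sorting for GFP would remove them and Lin28a (118 CPM in ESC-MN, 152 CPM in iPSC-MN) lies outside the pattern. Incomplete silencing in the neurons and a difference between the lines stay open and were not tested.

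Fibroblast and posterior Hox genes were both lower in ESC-MN and iPSC-MN than in E13.5 MN. For Hox genes of paralogs 9 to 13, other cells in E13.5 library 2 are argued against as the source, since the median log2 difference between the E13.5 libraries was 0.356 and 15 of 16 calls in ESC-MN and 15 of 15 in iPSC-MN stayed without library 2. For fibroblast genes the median was 2.61 (Col1a1 39.6 and 672 CPM), but 17 of 22 calls in ESC-MN and 12 of 22 in iPSC-MN stayed without library 2. Other cells in library 2 and a lower level in the cultured neurons cannot be told apart for these genes, since library 1 is then the only embryonic one. The age and axial level of the embryonic neurons may also play a part and were not tested.

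Fibroblast and interferon genes were higher in iMN than in E13.5 MN. Of 91 genes abundant in MEF and nearly absent from ESC-MN and iPSC-MN, 75.8% stood in iMN within 4-fold of a median 8.82% of their MEF level (quartiles 3.37% and 20.3%; 6.21%, 10.6% and 5.47% in libraries 1, 2 and 3, with the less strict gate in library 2), as fibroblasts in the libraries would need, by a small margin over the 75% set in advance; Col1a1 stood at 678 CPM and the fibroblast list at 24.1% (quartiles 12.1% and 40.6%). For the interferon list the median share was 68.3% (quartiles 29.9% and 82.4%), 7.75 times that of the 91 genes but 2.84 times that of the fibroblast list, so fibroblasts and a rise in the converted cells cannot be told apart for these genes. For them the less strict sorting gate of iMN library 2 is argued against, since 19 of 19 calls stayed without that library. Fibroblasts that passed the GFP sort and genes not silenced in converted cells both stay open for both lists. A response to retroviral transduction, which may raise interferon genes, was not tested.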

How the results depend on the processing

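All alternatives here were chosen before the data were examined. Among counts of changed genes and similarity values, 167 of 252 alternative values kept their direction and stayed within 1.5 times the main count or 1 SD. For the source cells' correlations this was 9 of 15 (the others moved by over 1 SD), for gene lists 974 of 1097 (107 no longer passed, 15 passed newly, 1 reversed), and for named genes 7034 of 7654 (303 no longer passed, 316 passed newly, 1 reversed). Both reversals came without E13.5 MN replicate 2: the median of the proliferation list, iPSC-MN vs E13.5 MN, was 0.0770 (-2.47 without replicate 1) and the log2 fold change of Mcm3, iPSC-MN vs E13.5 MN, was 0.0709 (-3.64 without replicate 1). RLE scaling and the fold threshold moved no total of changed genes beyond 1.5 times. The threshold left 1205 of 2106 higher genes for ESC-MN and 923 of 1507 for iPSC-MN against E13.5 MN, and 2017 of 3440 lower genes for iMN against ESC-MN.

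With only the compared groups in the fit, and so only their spread, the number of changed genes fell to 1513 for ESC-MN, 844 for iPSC-MN and 1114 for iMN against E13.5 MN, and to 0 for iPSC-MN and 4935 for iMN against ESC-MN. It rose to 3 for iPSC against ESC, 4792 for MEF media, 2369 for MEF passage and 132 for the line difference. With title style as a term it was 3331 for iPSC-MN against ESC-MN, 1794 for MEF media, 268 for MEF passage, 4453 for MEF age and 1032 for the line difference. By DESeq2 it was 2206 for iPSC-MN against ESC-MN, 2 for iPSC against ESC, 1475 for MEF media, 209 for MEF passage, 203 for conditioned medium, 1632 and 2162 for nCM and CM ESC-MN against E11.5 MN and 391 for the line difference. Without a filter it was 2 for iPSC against ESC, 115 for MEF passage, 1 for conditioned medium and 77 for the line difference. With replicate number as a block it was 0 for iPSC against ESC; the numbers do not pair the samples. An estimated correlation left 26 of 178 list calls. The cause was not tested.

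Leaving out 1 replicate in turn, where a lone library is assumed to vary like the other groups, gave 3836 to 7023 changed genes for ESC-MN and 1878 to 5041 for iPSC-MN against E13.5 MN, 38 to 4179 for iPSC-MN against ESC-MN, 0 for iPSC against ESC, 259 to 329 for MEF media, 3 to 18 for MEF passage, 4307 to 5192 for MEF age, 349 to 500 and 428 to 1504 for control-medium and conditioned-medium ESC-MN against E11.5 MN, and 1 to 2206 for the line difference. Shared calls ranged from 106 to 385 higher and 308 to 1060 lower, the correlation of conditioned medium with the line to E11.5 MN from 0.312 to 0.612, and that of the embryonic gap between library sets from 0.289 to 0.406. Fewer samples are part of each such setting, and beyond that the cause was not tested.

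The position of iPSC-MN was 0.876 without a filter, 0.867 with a prior count of 0.5, and 0.814 to 0.874 with 1 E13.5 library left out. Spearman correlations were 0.922 (ESC-MN), 0.936 (iPSC-MN) and 0.938 (iMN) without a filter, 0.929 for iPSC-MN with a prior count of 0.5, and 0.863 to 0.902, 0.899 to 0.930 and 0.899 to 0.905 with 1 E13.5 library left out. The order by correlation put iMN above iPSC-MN without a filter and without E13.5 MN replicate 1, and ESC-MN above iMN without E13.5 MN replicate 2. The cause was not tested. Depth limits what a count of 0 means: 3 counts per library correspond to 0.0778 to 0.468 CPM.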

Other observations

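Genes of the sex chromosomes differed between libraries in ways the labels do not describe. Their choice, and that of the other genes here, was made after their values were seen. The Y-linked Ddx3y stood at 0 CPM in both ESC-MN libraries, at 4.04 and 6.55 CPM in ESC, 13.8 and 15.3 CPM in iPSC, 28.2 and 25.9 CPM in iPSC-MN, 7.88 and 13.1 CPM in E13.5 MN and 20.8, 60.1 and 18.4 CPM in iMN. Xist, which silences an X chromosome in female cells, stood at 1.54 and 1.87 CPM in ESC-MN, 21.01 and 34.4 CPM in ESC, 2.42 and 1.77 CPM in iPSC-MN, 2799.6 and 1366 CPM in E13.5 MN and 2786, 818 and 1322 CPM in iMN.

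The motor neuron factor Isl2 stood at 5.07 and 69.4 CPM in the 2 iPSC-MN libraries and at 4.61 and 4.43 CPM in ESC-MN. Among the iMN libraries, library 2 had the complement gene C1qa at 22.1 CPM (0.582 and 5.31 CPM in the others), Gfap at 166 CPM (18.4 and 44.9 CPM) and Lcn2 at 235 CPM (6.99 and 22.9 CPM). In the conditioned-medium ESC-MN, library 1 had Lhx3 at 19.4 CPM and Nanog at 30.1 CPM, and library 2 had them at 107 and 7.55 CPM.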
